A study of Mus musculus with 4 samples.

How the data were processed

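Gene expression was measured by 10x Genomics 3-prime (version 3 chemistry, per the labels) single-cell RNA sequencing of cultured mouse islet suspensions of about 20000 cells each. The deposited matrices of the 2 TCDD libraries hold raw UMI counts per gene and barcode, without a barcode filter: 32285 genes and 6794880 barcodes, most of them empty. Per the file headers the counts were made with Cell Ranger 4, while the labels name Cell Ranger 2.1.0 and the genome build mm10; which version made them could not be settled. Of the gene identifiers, 32158 of 32285 were found in GENCODE M21, from which coordinates were taken. Where several identifiers share a symbol, the lowest one kept it, and 4 symbols of the gene lists were matched by synonym. The labels call the cells beta cells, but the suspension was of whole islets, so cells were classed by their genes. TCDD dose and exposure time are not in the labels. The 2 DMSO libraries were not analysed here, so the only comparison made was Malat1-null against wild type, both with TCDD.

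Barcodes were called as cells when they held at least 0.1 of the 99th percentile of UMIs among the top 3000 barcodes of their library, which gave minimums of 12368 UMIs in wild type and 14077 in Malat1-null and 1275 and 2134 barcodes. Cells with a mitochondrial share above 20% were to be removed, but the highest share was 9.85%. Scrublet, as run in scanpy 1.11.5, called 5 wild-type and 0 Malat1-null barcodes doublets, which were removed; how many doublets remain is not known. Cells of both libraries were clustered together on 2000 variable genes without Malat1, sex-linked and mitochondrial genes (30 principal components, 15 neighbours, Leiden at resolution 1 with igraph 0.11.9, no batch correction). A cluster of at least 40 cells in which 2 classes scored at least 0.6 was divided once at resolution 0.5.

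Clusters were named with 14 fixed marker lists: beta, alpha, delta, PP, endothelial, macrophage, T or NK, B cell, mesenchymal, acinar, ductal, Schwann, erythroid and granulocyte. A score per class was the mean over markers of the cluster's log2 CPM (with 10 CPM added), scaled from 0 to 1 over clusters. A cluster took the highest-scoring class if that score was at least 0.6 and at least 3 of its markers reached 20 CPM. It stayed unnamed if insulin stood beside another class, with Ins2 and another hormone, or Ins2 and a class other than beta, at 10% or more of the highest cluster. It also stayed unnamed if its 10 leading genes held more markers of another class (at least 3 against all other cells), or if its UMIs were low and none of its markers led. These limits were set after a first clustering had been seen and revised once, while the marker lists were fixed before the data were examined. No cluster was named Schwann, erythroid or granulocyte, and macrophages were named at minimums of 1000 and 5000 UMIs and, in wild type, with each library clustered alone, but not in the setting used here. The mesenchymal-like cluster led with Il11, Igfbp5 and F3, with none of its markers among the 10 leading genes. Shares of cells have exact (Clopper-Pearson) binomial intervals.

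UMIs were summed per gene over the cells of each class and library and scaled to CPM with TMM factors (edgeR 4.0.16, R 4.3.3). Levels have exact Poisson intervals and ratios exact conditional intervals at 95%, which cover counting error only; a single library per group allows no test, p-value or spread between animals. A gene counted as 2-fold apart if it had at least 50 CPM in a library and at least 50 UMIs over both, a ratio beyond 2-fold and an interval beyond 1.5-fold. In simulated data 200 genes of wild-type beta-like cells were changed. Among genes that met these minimums, 100% of the 3-fold changes, 0% of the 1.5-fold ones and 0 of 1314 unchanged genes were counted. The 0% follows from the 2-fold rule, and the simulated counts varied by counting error only. Lower bounds against a count of 0 use a floor of 3 counts.

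Gene lists fixed before the data were examined, 24 in number, cover AhR targets, Nrf2 targets, antioxidant enzymes, ER stress, beta identity and secretion, dedifferentiation, ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded genes, glycolysis, heat shock, immediate-early genes, p53 and apoptosis, interferon, MHC class I, NF-kB inflammation, splicing and speckles, long non-coding RNAs, neighbours of Malat1, cholesterol synthesis, proliferation, sex-linked genes, substrain genes and hypoxia. Some lists share members, such as Neat1, which is on those of the long non-coding RNAs and of the neighbours of Malat1. For members with at least 10 CPM in a library the median log2 ratio (0.5 UMIs added) was placed among 10000 random lists of the same size, drawn for each member from the 100 genes nearest in expression; a list needed 3 members. These percentiles are descriptive. Lists were compared in beta-like and alpha-like cells.

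Genes were named by a rule written before the data were examined: Malat1; the 12 highest and 12 lowest ratios in beta-like cells among genes with at least 50 CPM and 50 UMIs, leaving out Malat1, mitochondrial genes, sex-linked genes and markers of other classes; up to 4 members of each list with the largest ratios in either direction and at least 50 CPM in a library; AhR targets with at least 10 CPM; and, in any further class with at least 50 cells in both libraries, the 5 highest and 5 lowest, which no class met. Named outside the rule, after their values were seen, were the list members Ifit1, Irf1, Bbc3, Serpina7, Fabp5, Cd81, Pcna, Wdfy1 and Ide, Cxcl1 in alpha-like cells, AhR targets and Ddx3y and Xist below those levels, Spp1 as the marker among the 2-fold genes, genes leading clusters, and the genes followed across classes. Single values of some genes that the rule or the lists take in are not reported here; the lists keep them as members.

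Alternatives fixed before the data were examined were minimums of 1000 and 5000 UMIs, mitochondrial limits of 10% or none, doublets kept, each library clustered alone, Leiden resolution 2, total-count CPM, CPM without hormone, mitochondrial and Malat1 UMIs, DESeq2 1.42.0 size factors, subtraction of the free-RNA profile of barcodes with 10 to 99 UMIs (0.535% of UMIs in wild-type and 1.81% in Malat1-null beta-like cells, the most that Sst allowed), cells thinned to 20000 UMIs (alpha-like cells to 10000), and other CPM minimums. Added after seeing the data were beta-like cells without 2 clusters led by a marker of another class, beta-like cells without the cluster led by Hspa1a, mixed clusters kept as beta-like, 2 single clusters, and Cyp1a1 in endothelial-like cells under the settings for cells and scaling. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.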

Results

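Pancreatic islets of C57BL/6 mice, wild type or lacking the long non-coding RNA Malat1, were cultured, treated with the solvent DMSO or with TCDD, dispersed into single cells and profiled with 10x Genomics 3-prime single-cell RNA sequencing. TCDD is a dioxin that activates the aryl hydrocarbon receptor (AhR), a transcription factor that induces Cyp1a1. The series has 4 samples, 1 library for each genotype and treatment. The 2 TCDD libraries were compared, and the 2 DMSO libraries were not analysed here, so no effect of TCDD itself was measured. The wild-type library held 81872519 UMIs (unique transcript molecules) and 1270 cells, with a median of 53561 UMIs and 5842 genes per cell. The Malat1-null library held 134950186 UMIs and 2134 cells, with a median of 47557.5 UMIs and 5140 genes per cell. With 1 library per group there are no replicates, so nothing was tested for a genotype effect; intervals are 95% and cover counting error only.

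Malat1, an abundant nuclear RNA, was nearly absent from the Malat1-null library. In beta-like cells Malat1 (ENSMUSG00000092341; mm10 chromosome 19, 5795690 to 5802672, minus strand, annotated as a lincRNA) stood at 9078 CPM (UMI counts scaled to library size; interval 9054 to 9102) in wild type and at 0.295 CPM (0.195 to 0.430) in Malat1-null, from 552218 and 27 UMIs. The level was 30739-fold lower in Malat1-null (interval 21127 to 46646). At least 1 Malat1 UMI was found in 99.9% of wild-type beta-like cells (exact binomial interval 99.4 to 100%) and in 1.20% of Malat1-null ones (0.742 to 1.82%), at medians of 62559.5 and 48885 UMIs per cell. Endothelial-like cells had 14745 CPM and 4.45 CPM (2 UMIs), and B-cell-like cells had 19161 CPM and 0 UMIs.

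Both libraries were mostly insulin-producing beta-like cells, which were 68.8% of wild-type cells (874 cells; interval 66.2 to 71.4%) and 82.2% of Malat1-null cells (1755 cells; 80.6 to 83.8%). The Malat1-null library held smaller shares of the clusters named ductal, mesenchymal, endothelial and acinar. Ductal-like cells were 6.54% against 0.281%, mesenchymal-like cells 3.70% against 0.515%, endothelial-like cells 3.15% against 0.890%, and enzyme-secreting acinar-like cells 1.89% against 0.281%. None of the mesenchymal markers was among the leading genes of the mesenchymal-like cluster, which scored 0.96 for that class and 0.75 for ductal. No cluster was named mesenchymal at a minimum of 1000 UMIs or at Leiden resolution 2. Whether the Malat1-null library held fewer stromal cells was therefore not settled. The other hormone cells were nearer to each other: glucagon-producing alpha-like cells were 2.13% and 2.39%, somatostatin-producing delta-like cells 1.81% and 2.44%, and pancreatic-polypeptide (PP)-like cells 2.36% and 1.27%. B-cell-like cells were 4.09% and 2.06%, and T- or NK-like cells 1.18% and 0.187%. Clusters left unnamed held 4.33% of wild-type and 7.45% of Malat1-null cells. The UMI minimum and the clustering set these shares. With all barcodes of at least 1000 UMIs, beta-like cells were 44.2% and 61.9%, T- or NK-like cells 14.2% and 5.37%, and acinar-like cells 12.8% and 1.45%. B-cell-like cells were then 9.29% and 10.7%, ductal-like cells 6.40% and 0.585%, and unnamed cells 4.19% and 11.4%. In that setting wild-type acinar-like barcodes held 493 CPM of the nuclear RNA Malat1, against 9041 CPM in wild-type beta-like ones. Whether these acinar-like barcodes were whole cells was not tested, and they enter the shares. With each library clustered alone, the Malat1-null library gave no cluster named ductal, mesenchymal, delta or PP, where wild type had 36, 66, 23 and 28 such cells; B-cell-like cells were 2.28% and 3.33%, acinar-like cells numbered 24 and 16, and no T- or NK-like cluster was named. At Leiden resolution 2 ductal-like cells were 9.37% and 0.422%, delta-like cells 1.57% and 1.27%, and no cluster was named mesenchymal. Expression of sex-linked genes was of the male kind in both libraries: the Y-linked gene Ddx3y stood at 43.2 and 46.7 CPM in beta-like cells, and Xist, the RNA of the inactive X chromosome, at 0.0986 and 0.186 CPM.

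**Figure D1:**
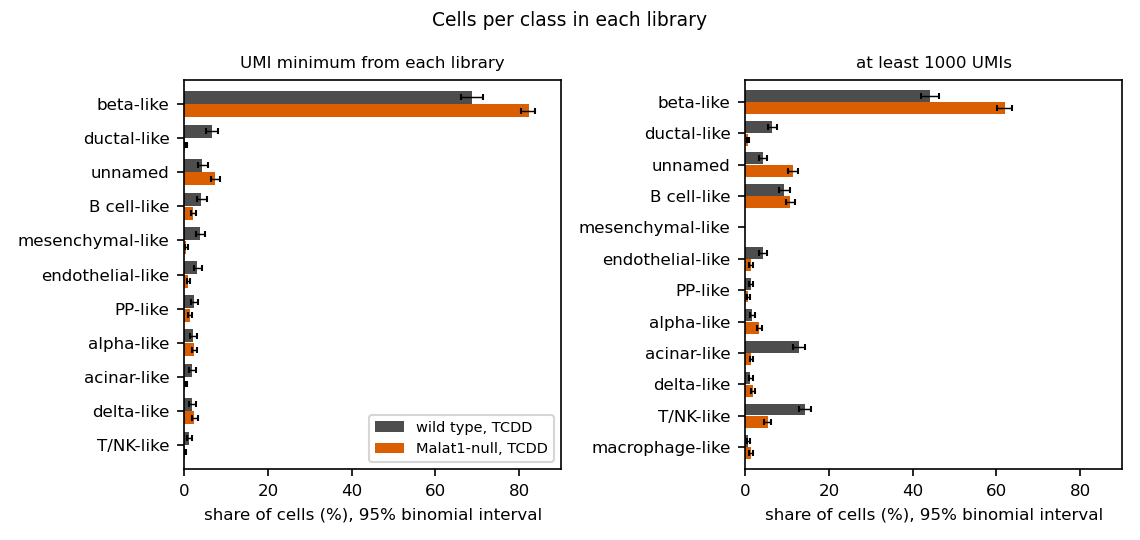
Share of cells (%, horizontal axis) in each cell class (vertical axis) in the wild-type and the Malat1-null TCDD library, with exact 95% binomial intervals, for cells above each library's own UMI minimum and for all barcodes with at least 1000 UMIs. Beta-like cells were 68.8% and 82.2% of cells in the first setting and 44.2% and 61.9% in the other, which gave no mesenchymal-like cluster.

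Which genes differ between beta-like cells with and without Malat1 under TCDD was asked next. Genes of mature beta cells were among those with the highest ratios of Malat1-null to wild type. Slc2a2, the glucose transporter of rodent beta cells, was at 36.7 CPM in wild type and 100.3 CPM in Malat1-null, a ratio of 2.73 (interval 2.61 to 2.86). The insulin-gene activator Mafa had a ratio of 1.97 (1.93 to 2.02) and Ucn3, a peptide of mature beta cells, one of 1.74 (1.68 to 1.80). Tmsb15b2, a thymosin gene also among the leading genes of the alpha-like cluster, had the highest ratio, 4.20 (4.00 to 4.41), followed by Enpp2, which makes lysophosphatidic acid, at 3.02 (2.84 to 3.21), and by Ppp1r1a, a phosphatase inhibitor, at 2.66 (2.57 to 2.76). Nfkbia, which encodes the NF-kB inhibitor, went from 113 CPM to 240.4 CPM, a ratio of 2.13 (2.07 to 2.19). The rest of the 12 highest ratios, those of Rnase4, Sytl4, Ypel3, Tra2b and Midn, lay between 1.68 and 1.91.

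Several stress-inducible genes were among those with the lowest ratios. The heat-shock genes Hspa1a and Hspa1b were at 70.2 and 59.0 CPM in wild type and at 7.80 and 6.77 CPM in Malat1-null, which is 9.0-fold (8.31 to 9.76) and 8.72-fold (8.0 to 9.51) lower. One cluster of 38 wild-type and 4 Malat1-null cells (4.35% and 0.228% of beta-like cells) was led by Hspa1a, Hspa1b and Dnajb1, and without it the log2 ratios were -0.58 and -0.98. The metallothioneins Mt1 and Mt2, which bind metals and scavenge oxidants, were 2.77-fold (2.75 to 2.78) and 2.90-fold (2.86 to 2.93) lower, with Mt1 at 5793 and 2094 CPM. The AP-1 genes Fos and Jun were 3.03-fold (2.93 to 3.14) and 2.29-fold (2.23 to 2.35) lower. Pdyn, which encodes prodynorphin, was 3.51-fold lower (3.37 to 3.66), the cytokine gene Mif went from 436 to 162 CPM, and the glycolytic enzyme gene Eno1 was 2.17-fold lower (2.09 to 2.26). The other genes among the 12 lowest were Rgs4, Fam162a and Rnaset2a, between 2.18- and 2.48-fold lower.

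Of 1639 genes with at least 50 CPM in 1 of the libraries, 5 were at least 2-fold higher in Malat1-null beta-like cells and 16 at least 2-fold lower, Malat1 included, with an interval beyond 1.5-fold. These counts were 14 and 32 when CPM left out hormone, mitochondrial and Malat1 UMIs, which raises every CPM so that more genes reach 50 CPM. The median log2 ratio of the same 1639 genes was 0.029 with that scaling. The counts were 10 and 20 with mixed clusters kept as beta-like, 8 and 19 at 1000 UMIs, and 9 and 19 at 5000 UMIs. Among genes with at least 20 CPM they were 12 and 34. One of the 16 was a marker of another class: the ductal marker Spp1 stood at 581 CPM and 78.6 CPM, 7.40-fold lower. The beta-like cells of the 2 libraries, clustered together without batch correction, were largely in different clusters. Technical differences between the libraries and differences between the cells cannot be told apart in this split. Most wild-type ones were in a cluster led by Pdyn, Serpina7 and the hypoxia gene Bnip3 (30.5% of wild-type and 2.39% of Malat1-null beta-like cells), in one led by Glul, Slc40a1 and Glp1r (21.4% and 6.72%), and in one led by Mt2, Mt1 and Hspb1 (13.0% and 9.46%). Most Malat1-null ones were in clusters led by Slc2a2, Ppp1r1a and Ucn3 (1.37% and 21.7%), by Gem, Nfkbia and Cebpd (3.43% and 19.2%), and by Rnase4, Mlxipl and Glp1r (3.66% and 17.8%). The Pdyn cluster and another, with 7.78% of wild-type and 1.54% of Malat1-null beta-like cells, had more markers of another class (Spp1; the PP markers Aqp4 and Folr1) than of their own among their 10 leading genes against all other cells, while against clusters of other classes they led with beta markers; without both, 4 genes were 2-fold higher and 14 lower. Compared within the Glul cluster alone, 3 genes were at least 2-fold higher and Hspa1b was higher in Malat1-null, at a log2 ratio of 0.22. Within the Mt2 cluster alone, 18 genes were higher and 8 lower, and Sytl4 was lower, at -0.22. Clusters were made from the same expression values. Comparing within a cluster thus matches cells on its leading genes and cannot decide on differences in them. With total-count scaling the median log2 ratio of the 1639 genes moved to -0.16, from 0.02 with the scaling used here.

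**Figure D2:**
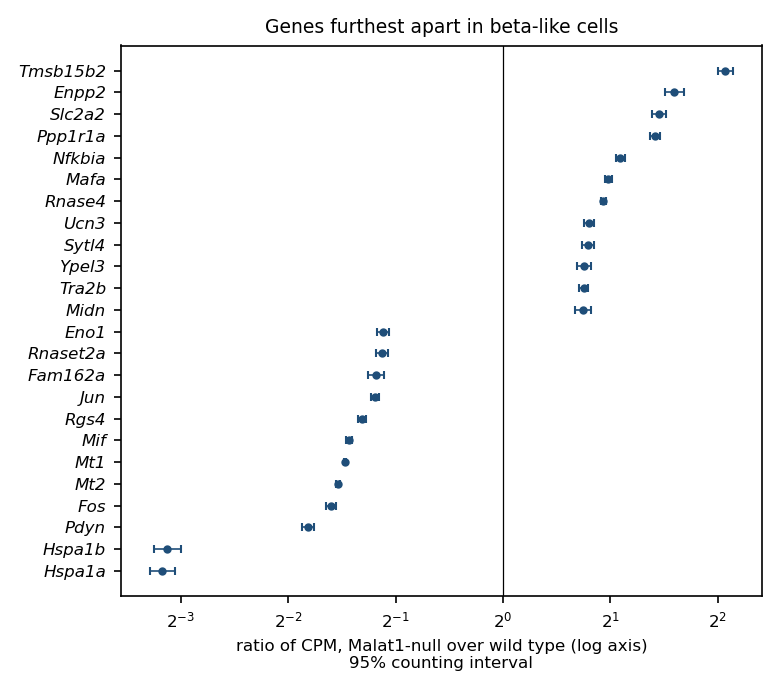
Ratio of CPM in Malat1-null over wild-type beta-like cells (horizontal log axis) for the 12 genes with the highest and the 12 with the lowest ratio (vertical axis); points are ratios and bars 95% counting intervals. Values run from 9.0-fold lower for Hspa1a to a ratio of 4.20 for Tmsb15b2.

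The series concerns oxidative stress in islet cells, so lists of stress genes fixed before the data were examined were compared in beta-like cells. Percentiles place a list's median log2 ratio among 10000 random lists matched on expression. The oxidative-stress lists moved little as groups. All 20 measured targets of Nrf2, the transcription factor of the oxidative-stress response, were within 1.5-fold (median 0.11, percentile 94.6), with Gstm1 and Sqstm1 each at a ratio of 1.26, and Txn1 at 1.16-fold lower. Of 19 antioxidant enzymes and related genes, 15 were within 1.5-fold, 1 was higher and 3 were lower (median -0.05, percentile 10.0). Those 3 were Mt1, Mt2 and Txnip, a thioredoxin inhibitor that went from 109 to 55.1 CPM, and Gpx1 was 1.29-fold lower.

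Glycolysis, hypoxia, heat-shock and immediate-early genes were lower in Malat1-null beta-like cells. Of 12 glycolysis genes 7 were at least 1.5-fold lower and none as much higher (median -0.72, percentile 0), among them Eno1, Pgk1 at 2.05-fold, Pgam1 at 1.75-fold and Tpi1 at 1.71-fold. Of 7 hypoxia-induced genes 5 were lower (median -0.81, percentile 0): besides Mif, Bnip3 was 1.99-fold and Ero1l 1.75-fold lower, while Vegfa, the vascular growth factor, was 1.07-fold lower. Of 14 heat-shock genes 5 were lower (median -0.24, percentile 0), with Hspb1 2.16-fold and the chaperone Hsph1 1.69-fold lower beside Hspa1a and Hspa1b; without the cluster led by Hspa1a the median was -0.047, at percentile 14.5. Of 14 immediate-early genes 5 were lower and 1 higher (median -0.35, percentile 0), with Dusp1 1.47-fold lower and Junb at a ratio of 1.59. Without the Pdyn cluster and the one with PP markers, the glycolysis and hypoxia medians were -0.14 and -0.16, at percentiles 0.81 and 2.22, and the heat-shock and immediate-early ones -0.39 and -0.48. Within the Glul cluster Junb was lower (-0.19) and Ero1l and Vegfa were higher (0.22 and 0.070). Within the Mt2 cluster Hspb1 and Dusp1 were higher (0.019 and 0.18). Hspb1 is among the genes leading the Mt2 cluster, and clusters were made from the same values, so these ratios do not decide on the lists.

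Genes of the endoplasmic reticulum (ER), of beta-cell identity and of the mitochondrial genome were higher as groups. Of 26 genes of ER stress, 3 were at least 1.5-fold higher and none lower (median 0.20, percentile 99.99), with Ppp1r15a at a ratio of 1.59, the stress transcription factor Atf4 at 1.57, Herpud1 at 1.41 and Dnajb9 at 1.36. Of 34 genes of beta-cell identity and secretion, 4 were higher and 1 lower (median 0.16, percentile 99.9; -0.022 with total-count scaling); the lower one was Chgb, a granule protein gene, 1.97-fold lower, and 0.036 higher on the log2 scale within the Mt2 cluster. Of 3 measured dedifferentiation genes, Serpina7 and Fabp5 were 3.42- and 2.13-fold lower and Cd81 had a ratio of 2.28 (median -1.09, percentile 0.25). The 13 mitochondrially encoded genes were all within 1.5-fold (median 0.21, percentile 99.8), with mt-Nd3 at 1.46 and mt-Nd1 at 1.25. The 77 nuclear genes of oxidative phosphorylation had 1 member higher and 76 within 1.5-fold (median -0.10, percentile 0), with Ndufc2 1.42-fold lower.

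Among inflammation genes, the 6 of the NF-kB list had a median of 0.29 (percentile 99.4), with Nfkbia higher, the interleukin receptor gene Il1r1 at a ratio of 1.21 and Nfkbiz at 0.982; the median was -0.013 within the Mt2 cluster. The 8 antigen-presentation (MHC class I) genes were within 1.5-fold (median -0.22, percentile 0.31), with Psmb8 1.36-fold and H2-D1 1.25-fold lower. Of 5 interferon-induced genes, Ifit1 was 2.39-fold lower and Irf1 had a ratio of 1.63 (median -0.17, percentile 6.38), and Ifi27 was 1.36-fold lower. Of 9 p53 and apoptosis genes, 8 were within 1.5-fold and 1, Bbc3, was higher at 1.63 (median 0.14, percentile 94.5); Cdkn1a was at 1.01 and Bax at 0.990.

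Malat1 concentrates in nuclear speckles, where splicing factors are stored. Of 24 splicing and speckle genes 23 were within 1.5-fold (median 0.13, percentile 99.6; -0.044 with total-count scaling); the other was Tra2b, a splicing regulator, at 1.68, and Clk1 and Srsf5 were at 1.39 and 1.27. Of 11 other long non-coding RNAs, 10 were within 1.5-fold and 1 was lower (median 0.02, percentile 49.3), with Rian at 1.44. Neat1, the neighbour of Malat1 on chromosome 19 and the core of paraspeckles, was 1.41-fold lower, from 119 to 84.7 CPM, and 0.26 higher on the log2 scale within the Mt2 cluster. The 5 measured neighbours of Malat1 had a median of 0.32 (percentile 98.8). The 11 cholesterol-synthesis genes were within 1.5-fold (median 0.21, percentile 99.6), as were the 80 ribosomal protein genes (median -0.09, percentile 1.10; 0.13 within the Mt2 cluster). The only proliferation gene measured was Pcna, 1.11-fold lower (1.04 to 1.19), while a beta-like cluster led by Stmn1, Ube2c and Lockd, with Top2a and Mki67 next, held 0 of 874 wild-type and 8 of 1755 Malat1-null beta-like cells. Of genes known to differ between C57BL/6 substrains, Wdfy1 had a ratio of 3.07 (2.80 to 3.37) and Ide was 2.20-fold lower (2.06 to 2.35). In all, 7 lists lay above the central 95% of random lists and 8 below it. Within the Glul cluster these counts were 4 and 3, and 4 lists lay above the central 95% with members of at least 50 CPM. Random lists were drawn gene by gene, while members of a list can vary together. Small medians, such as -0.09 for the ribosomal protein genes, can therefore reach extreme percentiles.

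**Figure D3:**
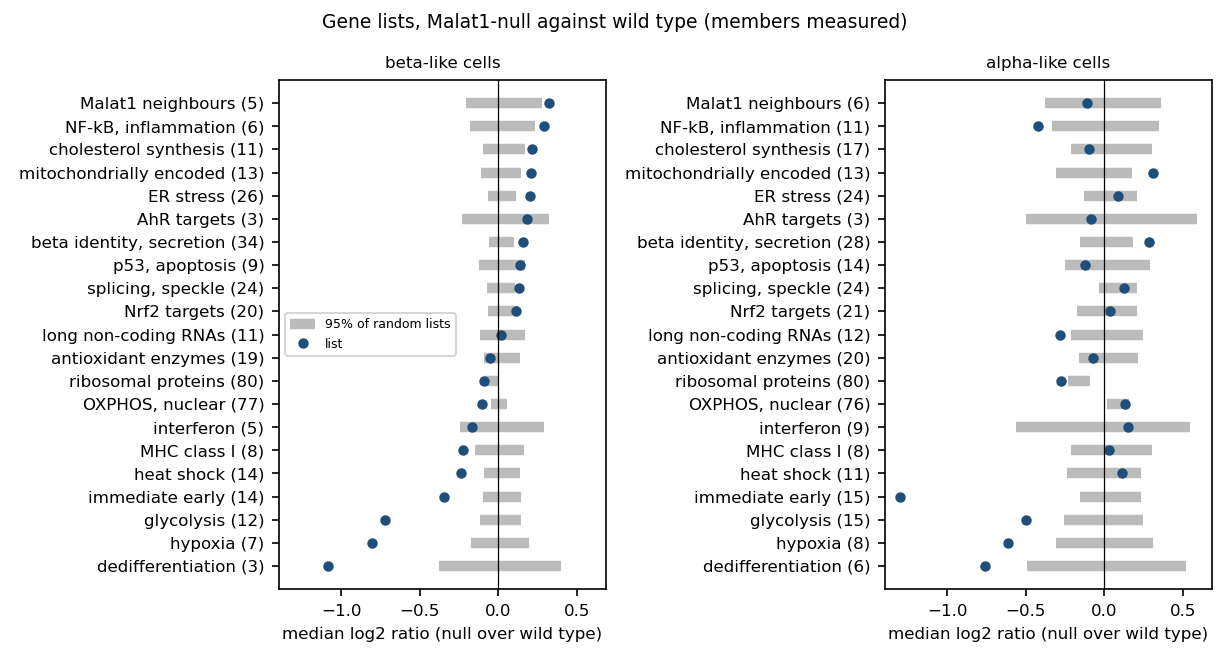
Median log2 ratio of Malat1-null over wild type (horizontal axis) for each gene list (vertical axis, members measured in parentheses) in beta-like and alpha-like cells; points are lists and grey bars the central 95% of random lists matched on expression. In beta-like cells the glycolysis and hypoxia medians were -0.72 and -0.81, and in alpha-like cells the immediate-early median was -1.30.

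Targets of AhR were followed class by class in the TCDD-treated islets. Cyp1a1, the xenobiotic-metabolising enzyme that AhR induces, was among the most abundant transcripts of endothelial-like cells of both genotypes and led that cluster's genes. It stood at 4379 CPM (4251 to 4510) in wild type and 5365 CPM (5153 to 5583) in Malat1-null, a ratio of 1.22 (1.17 to 1.29), and was seen in 87.5% of 40 cells (73.2 to 95.8%) and 100% of 19 (82.4 to 100%). The direction turned with the UMI minimum, to log2 ratios of -0.090 at 1000 UMIs and -0.021 at 5000, from 0.29. In endothelial-like cells Tiparp, a repressor of AhR, was at 491 and 305 CPM (ratio 0.621, 0.510 to 0.752), Nqo1, a quinone-reducing enzyme, at 137 and 218 CPM (1.59, 1.21 to 2.07), and Cyp1b1 at 39.5 and 8.90 CPM. Beta-like cells had 0.164 and 0.591 CPM of Cyp1a1, in 1.14% and 0.399% of cells. No Cyp1a1 UMI was found in alpha-, delta-, PP-, mesenchymal- or acinar-like cells; median depths were 21475.5 and 23066 UMIs per endothelial-like cell, and 27330 and 17123 per alpha-like cell. Of the 3 list members measured in beta-like cells, Socs2 went from 15.2 to 27.8 CPM (1.83, 1.70 to 1.97), Tiparp had a ratio of 1.14 (1.05 to 1.23; -0.37 on the log2 scale within the Glul cluster) and Arnt, the partner of AhR, one of 0.948 (median 0.18, percentile 84.5).

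Alpha-like cells, 27 in wild type and 51 in Malat1-null, allowed the same lists at lower depth. Immediate-early genes stood out: 13 of 15 were at least 1.5-fold lower in Malat1-null (median -1.30, percentile 0), with Fos 4.77-fold (3.79 to 6.04), the stress factor Atf3 8.29-fold (5.76 to 12.2) and Ier2 4.23-fold lower. Glycolysis genes were lower in 7 of 15 (median -0.50, percentile 0.02; Eno1 3.61-fold, 2.36 to 5.63) and hypoxia genes in 4 of 8 (median -0.61; Mif 2.03-fold). The NF-kB list had 4 of 11 lower and 2 higher (median -0.43, percentile 0.905; 0.27 with members of at least 50 CPM), with the chemokine Cxcl1 at 49.95 and 5.47 CPM and Nfkbia at a ratio of 1.56. Dedifferentiation genes had 3 of 6 lower (median -0.76, percentile 0.365; Fabp5 11.8-fold, 5.90 to 26.9), long non-coding RNAs 4 of 12 (median -0.28, percentile 0.66) and ribosomal protein genes 1 of 80 (median -0.27, percentile 0.08). Mitochondrially encoded genes had a median of 0.31 (percentile 99.9), and beta identity and secretion one of 0.29 (percentile 99.97), in cells where Ins2 itself was at 1368 and 10660 CPM. The medians of the other lists were within the central 95% of random lists: AhR targets -0.09, Nrf2 targets 0.04, antioxidant enzymes -0.07, ER stress 0.09, oxidative phosphorylation 0.13, heat shock 0.11, p53 -0.12, interferon 0.15, MHC class I 0.03, splicing 0.13, Malat1 neighbours -0.11, cholesterol synthesis -0.09 and proliferation 0.26. No other class except beta-like cells had 50 cells in both libraries.

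Markers of other cell types were counted in beta-like cells of both libraries, and whether they came from other cells was not tested. Acinar markers summed to 146 CPM in wild-type and 22.5 CPM in Malat1-null beta-like cells, ductal markers to 1288 and 731 (Spp1 alone 581 and 78.6), alpha markers to 889 and 979, PP markers to 707 and 613, delta markers to 61.8 and 95.3, and B-cell markers to 8.22 and 22.5. Barcodes with at least 100 and under 500 UMIs numbered 5619 in wild type, with 16.0% of their UMIs from insulin genes, and 48384 in Malat1-null, with 60.2%.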

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

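The tests on low-UMI barcodes, on the stress lists and on Wdfy1 and Ide were chosen after the results were seen.

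Malat1 UMIs appeared outside the called cells of the Malat1-null library. Barcodes of 10 to 99 UMIs, which gave the free-RNA profile, held 3603 of them, or 1602 CPM. The limit that a count of 0 allows is 3 counts. Free RNA from the Malat1-null cells is argued against, since the called cells held 0.402 CPM of Malat1, unscaled. Of 795 Malat1 UMIs on Malat1-null barcodes with at least 100 and under 500 UMIs, 63.0% (59.6 to 66.4%) were on barcodes that were cells in the wild-type library, against 1.59% of Ins2 UMIs. A candidate explanation is that reads of the wild-type library were assigned to the Malat1-null one; on barcodes of 10 to 99 UMIs the shares were 10.0% and 1.21%, so most of the UMIs there stay unexplained, and the wild-type DMSO library as their source was not analysed here. In the other direction, 13.7% of Ins2 and 0.300% of Malat1 UMIs on wild-type barcodes of 10 to 99 UMIs were on Malat1-null cell barcodes.

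Glycolysis, hypoxia, heat-shock and immediate-early lists were lower in Malat1-null beta-like cells, with medians of -0.72, -0.81, -0.24 and -0.35. With the free-RNA profile subtracted the glycolysis median was -0.72. In Malat1-null that profile held 1602 CPM of Malat1, against 0.402 CPM in called cells, so it is not only free RNA of these cells. The subtraction therefore cannot decide whether free RNA contributes to these lists. The heat-shock median was -0.39 without the 2 beta-like clusters that hold 30.5% and 7.78% of wild-type beta-like cells, so it does not come from their share. The glycolysis median was -0.14 without those 2, and the heat-shock median -0.047 without the cluster led by Hspa1a, but hypoxia genes are among those leading the larger of the 2, and heat-shock genes lead the other cluster, so a larger share of such cells and lower levels within cells cannot be told apart. At a minimum of 1000 UMIs the glycolysis and hypoxia lists lay below the central 95% of random lists in 8 and 7 of 10 classes. Their medians were -0.78 and -0.82 in B-cell-like and -0.63 and -0.90 in endothelial-like cells. Both lists lay within the central 95% in delta-like (0.14 and 0.014) and PP-like cells (-0.095 and -0.31). Handling or culture of 1 library may contribute to the glycolysis and hypoxia differences. It stays open for heat-shock genes (2 classes below and 2 above; 0.15 in B-cell-like and 0.038 in endothelial-like cells) and immediate-early genes (7 below and 1 above; -0.41 and 0.049), and so does loss of Malat1 acting in many cell types, untested with 1 preparation per genotype.

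Wdfy1 was higher and Ide lower in Malat1-null cells, both genes on the list of differences between C57BL/6 substrains. The Wdfy1 log2 ratio was 1.62 in beta-like cells and 1.63 with the free-RNA profile subtracted. That profile is not only free RNA of the Malat1-null cells, so the subtraction does not decide on free RNA. At a minimum of 1000 UMIs Wdfy1 was higher in 7 of 7 classes measured and Ide lower in 9 of 9, with an interval that leaves out 1 in 4 and 7 of these classes. A difference in genetic background and an effect of Malat1 on these genes cannot be told apart, because each genotype comes from 1 library.

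The NF-kB list differed in direction between classes, with medians of 0.29 in beta-like and -0.43 in alpha-like cells; the difference was not tested, and the alpha-like median was 0.27 with members of at least 50 CPM.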

How the results depend on the processing

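The alternatives fixed before the data were examined are the UMI minimums, mitochondrial limits, doublets, clustering, scaling, free RNA, thinning and CPM minimums; those of single, omitted or mixed clusters, and those of Cyp1a1, were chosen after the results were seen. No paired analysis was possible because each group has 1 library. The mitochondrial limits removed no cell and say nothing. Values under these limits stayed the same by construction and add to the counts of unchanged values. Of values per comparison, 121 under the alternatives stayed the same and 22 moved, and 2 reversed. Of those for single genes, lists and shares of cells, 1688 stayed the same, 386 moved beyond their counting interval, 21 became stronger and 30 weaker, and 24 reversed.

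Beta-like cells were 44.2% of wild-type and 61.9% of Malat1-null cells at 1000 UMIs, and 55.0% and 72.3% at 5000. Cyp1a1 in endothelial-like cells went from a log2 ratio of 0.29 to -0.090 at 1000 UMIs and -0.021 at 5000. For the Malat1 level by genotype, log2 ratios in beta-like cells were -14.91, at most -18.06 with free RNA subtracted (at the floor of 3 counts) and -13.91 in the Glul cluster alone. The subtraction says nothing here: 1.81% of a profile with 1602 CPM of Malat1 exceeds the 0.295 CPM measured. A count of 0 was thus fixed in advance.

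Genes 2-fold higher in Malat1-null beta-like cells numbered 5, against 8 at 1000 UMIs, 9 at 5000 UMIs, 14 without hormone, mitochondrial and Malat1 UMIs, 10 with mixed clusters kept, 3 in the Glul cluster, 18 in the Mt2 cluster, 12 at a minimum of 20 CPM and 1 at 200 CPM. Genes 2-fold lower numbered 16, against 32 without hormone, mitochondrial and Malat1 UMIs, 8 in the Mt2 cluster, 34 at 20 CPM and 7 at 200 CPM. The CPM minimums change these counts by the number of genes compared. Leaving out hormone, mitochondrial and Malat1 UMIs also changes that number, since it raises every CPM. Lists above the central 95% of random lists were 7, against 4 in the Glul cluster and 4 with members of at least 50 CPM; lists below it were 8, against 3 in the Glul cluster and 4 in the Mt2 cluster.

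With total-count CPM the signs turned of the beta identity (-0.022) and splicing (-0.044) medians and of Mcl1 (-0.010), as the median of all genes shifted too. In the Glul cluster alone they turned for Hspa1b (0.22), Gstm1 (-0.010), Fth1 (-0.17), Junb (-0.19), Ccng1 (0.052), Il1r1 (-0.067), Srsf5 (-0.039), Ero1l (0.22), Vegfa (0.070) and Tiparp (-0.37). In the Mt2 cluster alone they turned for the ribosomal (0.13) and NF-kB (-0.013) medians, Sytl4 (-0.22), Txn1 (0.25), Chgb (0.036), Rps25 (0.076), Hspb1 (0.019), Dusp1 (0.18), Ifi27 (0.025) and Neat1 (0.26). In alpha-like cells the NF-kB median was 0.27 with members of at least 50 CPM. Apart from the CPM minimums and the scaling shift, the cause was not tested. Clusters were made from the same values, so signs that turned within a single cluster do not decide on the results. Depth limits alpha-like and rarer classes most, with 27 alpha-like cells in wild type.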

Other observations

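The genes followed across classes, and the test of genes near Malat1, were chosen after the results were seen. At a minimum of 1000 UMIs, 8005 genes had at least 30 UMIs in at least 4 of 10 classes, and 6 had ratios at least 1.5-fold higher and 7, besides Malat1, at least 1.5-fold lower in Malat1-null in every class measured, with a count of 0 taken as 3 and whatever their intervals. Lrg1, a secreted glycoprotein of inflamed vessels and the acute phase, was 34.1-fold lower in beta-like cells (9.99 and 0.293 CPM; interval 23.0 to 52.6) and 6.51-fold lower in acinar-like cells (3.06 to 16.6), where genes in general were lower (median log2 ratio of 2686 genes -0.46). In ductal-like cells Lrg1 had 165 UMIs in wild type and 0 in Malat1-null (at least 3.15-fold lower), and in endothelial-like cells 39 and 0 (at least 5.82-fold lower). The ductal-like cells numbered 133 in wild type and 17 in Malat1-null. They held 269 and 425 CPM of the mesenchymal marker Rgs5, and no cluster was named mesenchymal in that setting. Whether a differing mix of cells in this class gave its ratios was not tested. Barcodes of 10 to 99 UMIs held 17.5 and 0.889 CPM of Lrg1. Ankrd37, a hypoxia-induced gene, was 7.65-fold lower in B-cell-like and 1.97-fold lower in beta-like cells, and Akr1b8, an aldo-keto reductase, was 3.45-fold lower in endothelial-like cells. The 6 higher genes were Slc7a8, Calb1, Nt5dc2, Rgs5, Mafa and Ppp1r1a. The last 2 are beta-cell genes that were counted in B-cell-like cells too, at 7 and 76 UMIs (Mafa) and 1 and 62 UMIs (Ppp1r1a). Barcodes of at least 100 and under 500 UMIs numbered 48384 in Malat1-null, with 60.2% of UMIs from insulin genes. In wild type they numbered 5619, with 16.0%. Whether free RNA of beta cells raised these 2 genes in other classes was not tested.

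At a minimum of 1000 UMIs the interferon list was higher in Malat1-null B-cell-like (median 0.74, percentile 99.99), T- or NK-like (0.41, 99.9) and macrophage-like cells (0.53, 97.9). It was lower in ductal-like cells (-1.18, 0.03), a class with 17 Malat1-null cells. The mix of ductal and mesenchymal cells in that class may differ between the libraries, which was not tested. The interferon median lay within the central 95% of random lists in acinar-like (-1.25), endothelial-like (-0.35), delta-like (-0.24), PP-like (-0.19), beta-like (-0.15) and alpha-like (0.12) cells. The interferon-induced chemokine Cxcl10 was higher in Malat1-null beta-like cells (1.52 and 6.62 CPM; ratio 4.36, 3.50 to 5.48) and alpha-like cells (5.07 and 41.7 CPM; 8.23, 3.39 to 26.0), and 2.04-fold lower in T- or NK-like cells. Differences between classes were not tested.

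One hypothesis was that a chromosome segment carried along with the Malat1-null allele makes nearby genes differ. The 110 genes within 10 Mb of Malat1 had a median size of log2 ratio of 0.14 in beta-like cells, at percentile 66.2 of random sets matched on expression. A median over 110 genes can stay low when few of them change, so it does not decide on a segment. The 5 fixed neighbours of Malat1 had a median of 0.32 (percentile 98.8) in beta-like cells, all within 1.5-fold, and Neat1 among them was lower. In alpha-like cells the neighbours measured had a median of -0.11 (percentile 27.0). A segment of any length stays open, as does an effect of the missing Malat1 locus on its neighbours.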
